A study of Mus musculus with 27 samples.

How the data were processed

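Gene expression was measured by RNA sequencing in 27 mouse samples of 8 groups. Of these, 15 were pieces of proximal small intestine and 12 were cultures of intestinal tumour organoids, which are clusters of epithelial cells grown in a gel. Per the labels' protocols, total RNA was extracted with a Qiagen kit, libraries were made with the Illumina TruSeq RNA kit and both ends of each fragment were read on an Illumina NextSeq. The kit as named does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

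Per the submitters' processing notes, the tools were bcl2fastq, TopHat2, SAMtools, HTSeq and DESeq2, and the builds were mm10 and GRCm38. Their versions, their roles, the annotation and the samples that were scaled together are not given in the sources used here. The deposited table held 37713 genes, of which 37607 identifiers were found in GENCODE release M21, the source of the coordinates printed here (GRCm38, counted from 1). For the 7 samples of the Slc7a5 experiment the values the authors deposited are a signal, gene counts divided by 1 size factor per sample. In each of these columns every value was a whole multiple of 1 step (100% of values within a tolerance of 0.05), so the whole reads behind it were recovered. For the other 20 samples, of the rapamycin and organoid experiments, the deposited values are a score, read from their spacing as size-factor normalised counts that the authors rounded to whole numbers. The step of each of these columns was estimated from the spacing of the rounded values. The same estimate, made after rescaling and rounding the 7 exact columns, missed their true step by at most 0.039%. Dividing a rounded value by its step gives reads that are only approximate.

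The whole reads assigned to genes numbered 23.3 to 29.8 M per sample in the Slc7a5 experiment. Estimated reads numbered 11.1 to 42.9 M in the rapamycin experiment and 22.7 to 31.9 M in the organoids. Median ratios to the common centre differed between the experiments (0.885 to 0.902 in the Slc7a5 experiment, 0.909 to 0.935 in the rapamycin experiment and 1.12 to 1.16 in the organoids) and lay near 1 within each. The 3 experiments were therefore treated as scaled separately, and tests were made within an experiment or on differences formed within experiments. No 2 libraries were identical, and the lowest chi-square per gene between replicates was 15.5, far above sampling noise. The sex of each mouse was read from Xist and 4 Y-linked genes.

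The edgeR test set in advance for raw counts was kept as an alternative, because the deposited values were normalised. Values were tested on the log2 scale with a pseudocount of 1, with limma 3.58.1 (trended prior) in R 4.3.3, for genes with a mean of at least 10 over the samples of a fit. This scale understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Slc7a5-deleted tissue was compared with its controls, and rapamycin with vehicle, in fits of those groups alone. The 12 organoid samples entered 1 fit with contrasts for each time and for the difference between the times. The difference between the deletion and rapamycin effects was tested in 1 fit of the 15 tissue samples. Gene lists, 32 in number with 686 entries, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. No list call in any of the 6 contrasts held with a correlation estimated from the data. Counts given as "adjusted over the list alone" used only the p-values of the list's own members.

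The named genes were Slc7a5, Slc3a2 and Kras, up to 4 members with the smallest adjusted p of each list that passed or held 3 or more changed genes, and the 2 most abundant members of any other list. To these came, in each direction, the 10 largest changes among genes past the threshold with a mean of at least 50 in the higher group and no overlap between replicate values, leaving out predicted genes. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were taken and are given as values. From this output the genes printed here were picked after their values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

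Fits on simulated counts, drawn with the real means, depths and dispersions, were used to test the code. They held 200 changed genes and a changed list of 30 more. Genes and samples were drawn independently, without differences between organoid lines or sexes, so the shares that follow may not hold for the real data. For the Slc7a5 deletion 52% of 2-fold and 84% of 4-fold changes were recovered, and for rapamycin 64% and 88%. In the organoids the shares were 37% and 70% at 24 h, 39% and 72% at 48 h, and 11% and 47% for the difference between the times. For the difference between deletion and rapamycin they were 33% and 80%.

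Organoid samples with the same replicate number deviated from their group means together, with correlations across genes of 0.764 to 0.891 for every pair, and the design text speaks of 3 lines. The numbers were therefore taken to pair the organoid samples, and results of a fit with the replicate number as a block are given after those without it. The tissue samples shared only a number. Alternatives covered the pseudocount, the filter, rescaling by median ratios or TMM factors, a robust prior, the block, other groups in the fit, leaving out each replicate, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0. The count tools ran on whole reads in the Slc7a5 experiment. On approximate reads of the other experiments they were added after seeing the data, as were sex as a covariate and the lists without each replicate. Organoid samples were left out singly from the fit without the block. The partner samples with the same number then stayed in, so shifts there can reflect differences between the replicate numbers. Figures were drawn with matplotlib 3.10.9.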

Results

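The samples came from mice and organoids in which Apc was deleted and a mutant Kras allele was present in the intestinal epithelium (the genotype called AK here). Loss of Apc switches on Wnt signalling, and mutant Kras drives the MAPK pathway. The Slc7a5 experiment held 3 AK tissue samples and 4 from mice of that genotype in which Slc7a5 was deleted as well. The rapamycin experiment held 4 AK tissue samples from mice given rapamycin, an inhibitor of the growth regulator mTORC1, at 10 mg/kg and 4 given vehicle. The organoid experiment held 3 samples each of the conditions called plus and min in the labels, at 24 and 48 h. These are read here as with and without doxycycline, the drug that the design text names. That text calls the lines Apc iKras, while the labels give the organoids the AK genotype, so what the drug switched on is not settled here. Values are normalised read counts, given as mean ± SD. The design text says that tissue came from separate animals and organoids from 3 lines, but it states 3 animals per genotype where 4 deleted samples exist. Beyond these words nothing shows where each replicate came from, and p-values measure the spread between these samples.

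Slc7a5 encodes the transporter of large neutral amino acids that pairs with Slc3a2 at the cell surface. It stood at 2613, 2779 and 3443 normalised counts in the AK tissues and at 606, 1775, 771 and 1303 in the deleted tissues, so that every deleted sample lay under every AK sample. The means were 2945 ± 440 (n = 3) and 1114 ± 532 (n = 4), a log2 fold change of -1.52. Over all genes its adjusted p was 0.435 in limma and 0.00688 in DESeq2 on whole reads, and the two-sided exact permutation p was 0.0571 over 35 splits. Slc7a5 (ENSMUSG00000040010) lies on chromosome 8 from 121881150 to 121907694 on the minus strand. The partner Slc3a2 (chromosome 19, 8706882 to 8723369, minus strand) stood at 5495 ± 510 and 7064 ± 1873, adjusted p = 0.61. Kras (chromosome 6, 145216699 to 145250239, minus strand) stood at 2894 ± 203 and 3359 ± 312, adjusted p = 0.538.

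**Figure D1:**
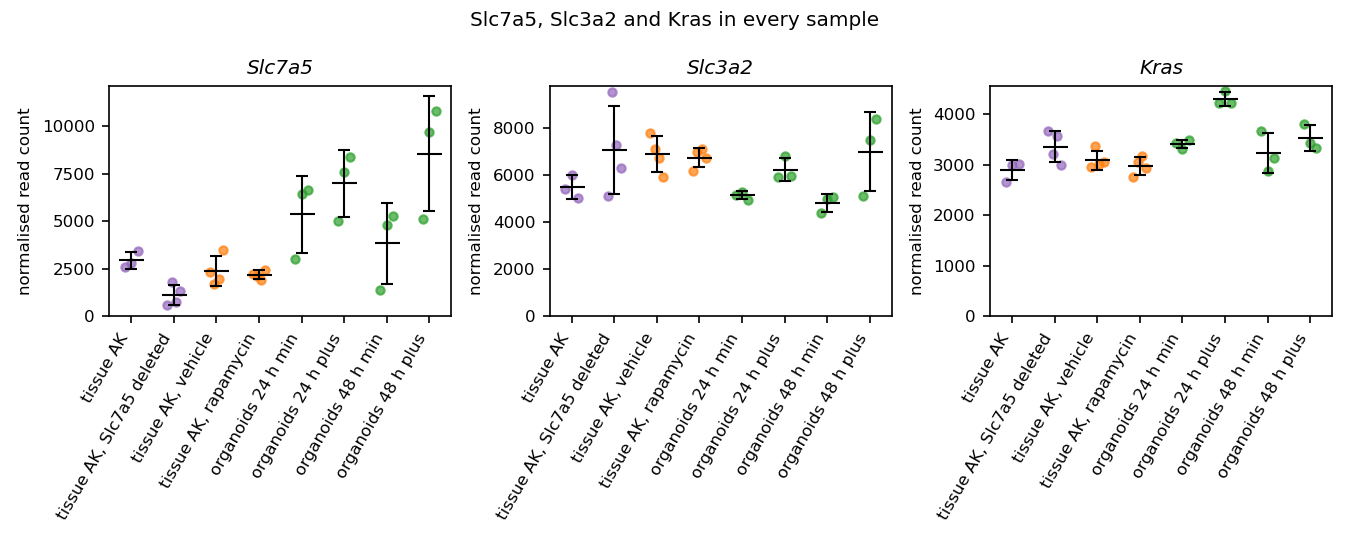
Normalised read counts (linear axis from 0) of Slc7a5, Slc3a2 and Kras in every sample of the 8 groups; points are samples, horizontal bars the mean and error bars the SD. The 4 Slc7a5-deleted tissues sit between 606 and 1775 for Slc7a5, under all 3 AK tissues, and levels are comparable only within an experiment (purple, orange, green).

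In Slc7a5-deleted tissue, targets of ATF4, the transcription factor that answers amino acid shortage, were higher as a group, and so were interferon response genes. Of 31 ATF4 list members 29 had a positive log2 fold change, with a median of 0.77 (camera adjusted p = 1.2e-10; adjusted p = 0.64 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, stood at 379 ± 45.8 (n = 3) in AK and 2103 ± 1134 (n = 4) in deleted tissue, and the stress factor Ddit3 at 297 ± 25.7 and 692 ± 225. Atf4 itself stood at 5616 ± 465 and 11870 ± 4245. No member passed over all genes in limma, and 7 passed with p adjusted over the list alone, all higher. Of 25 interferon response genes 24 were positive, with a median of 0.94 (adjusted p = 1.2e-10; adjusted p = 0.64 with an estimated correlation), among them Ifit1 at 410 ± 198 and 1293 ± 803 and the regulator Irf7 at 1836 ± 474 and 3086 ± 654. None of the 25 passed over the list alone.

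Markers of Lgr5 stem cells, the dividing cells at the crypt base, were lower in the deleted tissue. All 14 had a negative log2 fold change, with a median of -0.56 (adjusted p = 1.2e-10; adjusted p = 0.54 with an estimated correlation), and 7 passed with p adjusted over the list alone. The RNA-binding protein Msi1 stood at 1614 ± 47.9 (n = 3) in AK and 934 ± 131 (n = 4) in deleted tissue, Smoc2 at 5498 ± 105 and 3577 ± 432, and the water channel Aqp4 at 1926 ± 351 and 1051 ± 187. Genes of S phase and mitosis were lower by less, with 30 of 32 negative and a median of -0.22 (adjusted p = 8.6e-10; adjusted p = 0.64 with an estimated correlation). The mitotic checkpoint kinase Bub1 stood at 1006 ± 31.8 and 752 ± 43.4, and it alone passed over the list. Wnt and beta-catenin targets had a median of -0.23, with 17 of 21 negative (adjusted p = 0.0043; adjusted p = 0.64 with an estimated correlation), Lgr5 at 752 ± 146 and 453 ± 119. Goblet cell markers, of mucus-making cells, had a median of -0.58, with 13 of 14 negative (adjusted p = 0.00016; adjusted p = 0.64 with an estimated correlation), and 2 passed over the list alone. Without deleted replicate 2 the median was -0.14 for S phase, still past the threshold, and -0.11 for Wnt targets, no longer past it (adjusted p = 0.11). Without deleted replicate 4 that of goblet cells was -0.37, still past it.

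Several metabolic lists were higher in the deleted tissue in the fit without covariates. With sex as a covariate oxidative phosphorylation and glycolysis were not, as given below. All 30 oxidative phosphorylation genes were positive, with a median of 0.28 (adjusted p = 4.8e-09; adjusted p = 0.64 with an estimated correlation), among them Uqcrq at 5471 ± 277 (n = 3) and 7599 ± 1230 (n = 4). Of 20 glycolysis and hypoxia genes 19 were positive, with a median of 0.39 (adjusted p = 2.9e-05; adjusted p = 0.64 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.14, with 67 of 79 positive (adjusted p = 1.5e-05; adjusted p = 0.73 with an estimated correlation), and lysosomal genes a median of 0.14, with 22 of 25 positive (adjusted p = 0.0012; adjusted p = 0.64 with an estimated correlation). Enteroendocrine markers had a median of 0.33, with 14 of 18 positive (adjusted p = 0.00045; adjusted p = 0.64 with an estimated correlation), the hormones Cck at 188 ± 26.3 and 416 ± 176 and Sst at 382 ± 84.1 and 556 ± 65.7. Enterocyte markers (median 0.30, 22 of 25 positive, adjusted p = 0.033) and cytosolic tRNA synthetases (median 0.17, 15 of 20 positive, adjusted p = 0.049) passed as well; each had an adjusted p = 0.95 with an estimated correlation. The mTORC1 and insulin feedback list was lower, with a median of -0.15 and 14 of 20 negative (adjusted p = 0.041; adjusted p = 0.64 with an estimated correlation), although Grb10, a growth factor receptor adaptor, stood at 197 ± 46.2 and 560 ± 343. Single libraries ended some of these calls. Synthetases passed in 3 of 7 fits, not without AK replicate 1 (median 0.11) or deleted replicate 1 (0.14), 3 (0.10) or 4 (0.05), and had 0.39 without deleted replicate 2. The mTORC1 feedback list passed in 3 of 7 (not without AK replicate 1 or 2 or deleted replicate 1 or 2; median -0.12 to -0.20). Enterocytes passed in 5 of 7, not without AK replicate 3 (median 0.21) or deleted replicate 2 (0.02). Without deleted replicate 2 enteroendocrine cells (0.27), lysosomal genes (0.08) and Wnt targets (-0.11) did not pass either. Other medians moved while still past the threshold: without deleted replicate 2 to 0.16 for oxidative phosphorylation, 0.21 for glycolysis and 0.21 for ribosomal proteins. Ribosomal proteins had 0.08 without AK replicate 2 or deleted replicate 4, and lysosomal genes 0.22 without deleted replicate 1 or 4.

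Markers of other cells in the tissue did not pass in the fit without covariates. Medians were -0.03 for immune cells (adjusted p = 0.90), -0.03 for fibroblasts (0.84), 0.21 for smooth muscle (0.71), 0.07 for endothelium (0.67), 0.03 for enteric neurons and glia (0.82) and -0.37 for pancreatic acinar cells (0.20). Amino acid transporters as a group, with a median of 0.17 over 27 genes, did not pass either (adjusted p = 0.54). Smooth muscle had medians of -0.62 to 0.71 without single libraries. With the sex of the mice as a covariate, smooth muscle (median -1.46) and enteric neurons and glia (-0.51) passed as lower. The deletion effect in that fit rests on the 1 female deleted sample.

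In limma 0 of 16240 genes changed, against 153 in DESeq2 (74 higher, 79 lower) and 0 in edgeR, both on whole reads. At an unadjusted p under 0.05 limma counted 1582 genes, of which 904 were lower, where 812 were due by chance; edgeR counted 1622 and DESeq2 1737. The limma count was 306 with the sex of the mice as a covariate, so the excess over chance was not seen there. It was 851, 847 and 1033 without AK replicates 1, 2 and 3, 1054 without deleted replicate 3 and 2472 without deleted replicate 2. Past the threshold were 8 genes without deleted replicate 2 and 6 without deleted replicate 1. The smallest p belonged to Pparg, a lipid-sensing nuclear receptor (479 ± 35.3, n = 3, in AK and 856 ± 67.4, n = 4, in deleted tissue, limma adjusted p = 0.308), and to the clock gene Ciart (42.5 ± 5.60 and 151 ± 36.3, adjusted p = 0.308). Among genes with lower values, Cit, a kinase of cell division, stood at 987 ± 24.0 and 677 ± 26.4, and the DNA repair gene Fanca at 830 ± 93.8 and 419 ± 71.2, both with an adjusted p = 0.433. All 3 AK tissues were from females and 3 of the 4 deleted tissues from males. With sex as a covariate, a fit in which the deletion effect rests on the 1 female deleted sample, the medians were 0.68 for ATF4 targets, 0.50 for interferon, -0.30 for Lgr5 stem cells and -0.16 for S phase, all still past the threshold. In that fit the medians were -0.03 for oxidative phosphorylation (adjusted p = 0.65), -0.10 for glycolysis (0.65), -0.12 for enterocytes (0.48), 0.05 for enteroendocrine cells (0.40) and 0.06 for lysosomal genes (0.39) and -0.02 for Wnt targets (0.46), and none of these passed. Beside the 2 lists of other cells given above, 5 lists passed only with the covariate: regenerative epithelium (0.61, adjusted p = 0.016), p53 targets (0.38, 0.0045), ribosome biogenesis (0.15, 0.0018), cholesterol synthesis (-0.18, 0.00076) and fatty acid synthesis (-0.19, 0.0024).

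**Figure D2:**
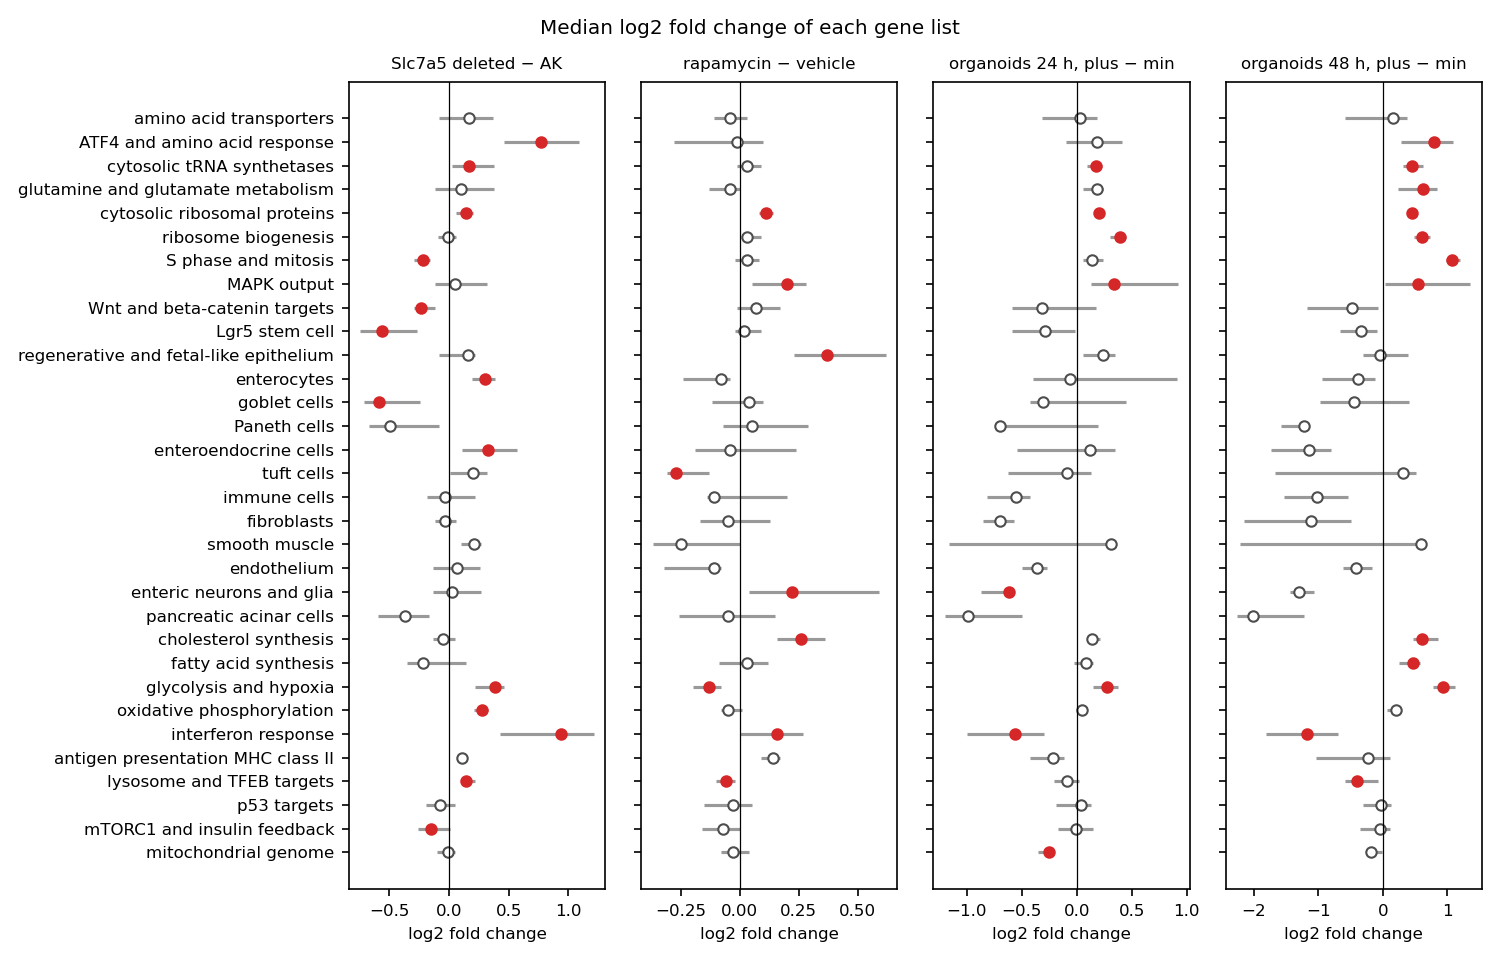
Median log2 fold change (points) and interquartile range over members (bars) of the 32 gene lists in the 4 main comparisons, each panel with its own axis; filled red points passed camera at an adjusted p under 0.05 with the preset correlation. ATF4 targets and interferon genes lie highest after Slc7a5 deletion (medians 0.77 and 0.94), and S phase genes highest in organoids at 48 h (1.08).

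Rapamycin was compared with vehicle in AK tissue to see what inhibiting mTORC1 did to the same mutant epithelium. Genes of cholesterol synthesis were higher as a group after rapamycin, with 23 of 24 positive and a median of 0.26 (adjusted p = 5.5e-21; adjusted p = 0.51 with an estimated correlation), and 13 passed with p adjusted over the list alone. Hmgcs1, which makes the precursor of mevalonate, stood at 6830 ± 554 (n = 4) with vehicle and 8412 ± 308 (n = 4) with rapamycin, Mvd at 1404 ± 202 and 1971 ± 245, and Lss at 2058 ± 221 and 2822 ± 418. Cytosolic ribosomal proteins were higher as a group, with 77 of 79 positive and a median of 0.11 (adjusted p = 7.6e-12; adjusted p = 0.94 with an estimated correlation). MAPK output genes had a median of 0.20, with 20 of 26 positive (adjusted p = 0.00027; adjusted p = 0.94 with an estimated correlation). Among them Fos, an immediate early transcription factor, stood at 3056 ± 244 and 4340 ± 175, with no overlap between samples, and it alone passed over the list. The ribosomal protein median was 0.04 without vehicle replicate 2 (adjusted p = 0.026), 0.17 without rapamycin replicate 3 and 0.18 without vehicle replicate 4. For MAPK output it was 0.10 without rapamycin replicate 1, 0.09 without vehicle replicate 2 and 0.35 without vehicle replicate 4, all past the threshold, and 0.08 without vehicle replicate 1, not past it (adjusted p = 0.057).

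Genes of regenerative and fetal-like epithelium had a median of 0.37, with 11 of 13 positive (adjusted p = 0.0018; adjusted p = 0.94 with an estimated correlation), Cyr61, a target of YAP signalling, at 345 ± 92.3 (n = 4) with vehicle and 577 ± 156 (n = 4) with rapamycin. The median was 0.16 for the interferon response (18 of 25 positive, adjusted p = 0.032; adjusted p = 0.97 with an estimated correlation). It was 0.22 for enteric neurons and glia (10 of 12 positive, adjusted p = 0.032; adjusted p = 0.94 with an estimated correlation), where the glial gene Gfap stood at 18.8 ± 9.18 and 50 ± 26.8. Tuft cell markers were lower, with a median of -0.27 and 11 of 13 negative (adjusted p = 0.032; adjusted p = 0.94 with an estimated correlation). Glycolysis and hypoxia genes had a median of -0.13 with 18 of 20 negative (adjusted p = 0.042; adjusted p = 0.97 with an estimated correlation). Lysosomal genes had a median of -0.06 with 21 of 25 negative (adjusted p = 0.032; adjusted p = 0.94 with an estimated correlation), Gpnmb, a glycoprotein of lysosomes, at 76.8 ± 4.99 and 42.5 ± 7.14. ATF4 targets (median -0.01, adjusted p = 0.51), Lgr5 stem cell markers (0.02, adjusted p = 0.63), S phase genes (0.03, adjusted p = 0.09) and the mTORC1 feedback list (-0.07, adjusted p = 0.072) did not pass. Cholesterol synthesis passed without any single library (median 0.22 to 0.31), and most other calls did not. The regenerative median was 0.15 without vehicle replicate 1, where it did not pass, 0.57 without rapamycin replicate 3 and 0.68 without vehicle replicate 4. The interferon call ended without rapamycin replicate 2 (median 0.06) or 4 (0.12) or vehicle replicate 1 (0.04) or 3 (0.12), and the median was 0.26 without rapamycin replicate 1 and 0.31 without vehicle replicate 2. The lysosomal call ended without rapamycin replicate 1 (-0.03) or 4 (-0.04) or vehicle replicate 1 or 2 (-0.04 each), with -0.09 without rapamycin replicate 3 and -0.11 without vehicle replicate 4. Neurons and glia did not pass without rapamycin replicate 1 (0.08), 3 (0.17) or 4 (0.20) or vehicle replicate 1 (0.08), and had 0.57 without rapamycin replicate 2 and 0.39 without vehicle replicate 2. Tuft cells did not pass without rapamycin replicate 1 (-0.24) or 4 (-0.15) or vehicle replicate 2 (-0.03), and had -0.40 without rapamycin replicate 3. Glycolysis did not pass without rapamycin replicate 1 (-0.09) or 4 (-0.08) or vehicle replicate 2, where its median turned to 0.05, and had -0.21 and -0.20 without vehicle replicates 1 and 4.

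Slc7a5 stood at 2368 ± 780 (n = 4) with vehicle and 2182 ± 230 (n = 4) with rapamycin, adjusted p = 0.996, and Slc3a2 and Kras likewise did not pass. In limma 0 of 15875 genes changed, and edgeR called 0 and DESeq2 14 (13 higher) on approximate reads. At an unadjusted p under 0.05 limma counted 511 genes, where 794 were due by chance; edgeR counted 519 and DESeq2 504. Without vehicle replicate 4 the limma count was 1671 and without vehicle replicate 3 it was 321, and with sex as a covariate it was 845, so its place under the chance value is not fixed. The smallest p with higher values, after Fos, belonged to the peptide hormone Apln at 210 ± 39.7 and 418 ± 55.1 and to Pla2g4c at 62.5 ± 4.12 and 114 ± 13.0, both with a limma adjusted p = 0.557. The calcium-binding gene S100g stood at 73.0 ± 28.3 and 186 ± 12.3 and the phosphatase Dusp1 at 288 ± 40.6 and 478 ± 58.9, adjusted p = 0.982 for each. Vehicle tissue came from 1 male and 3 females and rapamycin tissue from 2 males and 2 females. Clock genes differed between these groups too. Arntl stood at 464 to 585 with vehicle and 618 to 786 with rapamycin, and it alone of those looked at parted the groups fully. Nr1d2, at 808 to 1723 and 666 to 1267, overlapped. Time of day is not given in the labels, so its part in the rapamycin results was not tested. With sex as a covariate enteric neurons and glia (adjusted p = 0.12) and the interferon response (adjusted p = 0.28) no longer passed. MHC class II genes (median 0.45, adjusted p = 0.0023), ribosome biogenesis (0.07, 0.0098), Wnt targets (0.12, 0.025), S phase (0.05, 0.037) and enterocytes (-0.19, 0.047) passed only with it.

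The effects of the deletion and of rapamycin were set against each other, since amino acid supply and rapamycin both act on mTORC1. Across 15328 genes their log2 fold changes had a Pearson correlation of 0.069 and a Spearman correlation of 0.019, with the same sign in 51.2% of genes, which are not independent replicates. Without vehicle replicate 2 the Pearson value was 0.237, and it was negative without vehicle replicate 4 (-0.028), deleted replicate 3 (-0.013) or rapamycin replicate 3 (-0.010). In the test of the difference itself, 15 lists differed (8 higher and 7 lower after deletion than after rapamycin). ATF4 targets differed by a median of 0.78 with 30 of 31 positive (adjusted p = 1.4e-10; adjusted p = 0.47 with an estimated correlation) and interferon genes by 0.83 (adjusted p = 1.6e-06; 0.47 likewise). Oxidative phosphorylation differed by 0.29 (adjusted p = 1.8e-08; adjusted p = 0.52 with an estimated correlation) and glycolysis by 0.49 (adjusted p = 3.8e-06; 0.47 likewise). Cholesterol synthesis differed by -0.30 with 22 of 24 negative (adjusted p = 1.9e-09), S phase by -0.26 (adjusted p = 9.4e-10) and Lgr5 stem cells by -0.53 (adjusted p = 2.2e-08), each with an adjusted p = 0.47 with an estimated correlation. These 7 lists passed without any single library. The ATF4 median was then 0.48 without deleted replicate 3 and 0.52 without vehicle replicate 4. That of oxidative phosphorylation was 0.19 without deleted replicate 2 and that of glycolysis 0.29 without vehicle replicate 2. In the fit with sex as a covariate the glycolysis median was 0.28 and that of oxidative phosphorylation 0.20. With sex as a covariate enterocytes (median 0.26 against 0.41 without it, adjusted p = 0.14), enteroendocrine cells (0.27 against 0.49, adjusted p = 0.18) and tuft cells (0.32 against 0.47, adjusted p = 0.064) kept their direction but no longer passed. None of these 3 passed without deleted replicate 2 (0.11, 0.24 and 0.24) or vehicle replicate 2 (0.26, 0.32 and 0.27), nor did enterocytes without AK replicate 3 (0.26) or vehicle replicate 1 (0.31), and enterocytes had 0.64 without vehicle replicate 4. Before the covariate the adjusted p of the 3 was 0.012, 0.014 and 0.012, and 0.79, 0.62 and 0.55 with an estimated correlation. Synthetases (median 0.14, adjusted p = 0.02), ribosomal proteins (0.09, 0.017) and enteric neurons and glia (-0.43, 0.033) passed only with it. For single genes 0 of 16243 differed in limma, 0 in edgeR and 22 in DESeq2 on approximate reads. Without deleted replicate 2 limma called 7, and without rapamycin replicate 3 it called 2. At an unadjusted p under 0.05 the counts were 1187, 1248 and 1331, and 833 in limma with sex as a covariate.

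In organoids after 24 h in the plus condition, 6 of 14762 genes changed. Prm1, which encodes a protamine that packs DNA in sperm, rose from 1 ± 1 (n = 3) normalised counts in min to 376 ± 162 (n = 3) in plus, adjusted p = 0.000322. Manea, a mannosidase of the Golgi, rose from 604 ± 55.4 to 2262 ± 350, Sh2d5 from 322 ± 36.2 to 1115 ± 254, Mrc1, a mannose receptor best known from macrophages, from 34.7 ± 10.0 to 180 ± 13.0, and Plek2 from 1136 ± 130 to 2053 ± 178 (limma adjusted p = 0.00328, 0.00648, 0.047 and 0.047). Bik, which promotes cell death, fell from 161 ± 16.8 to 59.7 ± 3.79, adjusted p = 0.047. For each of the 6 the plus and min samples did not overlap, as chance gives for 10% of genes. Prm1 (ENSMUSG00000022501) lies on chromosome 16 from 10796326 to 10805839 on the minus strand. Kras stood at 3412 ± 86.4 in min and 4300 ± 146 in plus, a log2 fold change of 0.33 with an adjusted p = 0.412, and 0.0296 in the fit with the replicate number as a block.

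Genes of the MAPK pathway's output were higher in plus at 24 h, with 22 of 26 positive and a median of 0.34 (adjusted p = 1.2e-09; adjusted p = 0.80 with an estimated correlation), and 8 passed with p adjusted over the list alone. The phosphatase Dusp6, a feedback inhibitor of ERK, stood at 2526 ± 214 (n = 3) in min and 4806 ± 577 (n = 3) in plus, the transcription factor Fosl1 at 512 ± 151 and 1629 ± 403, and the receptor Epha2 at 15150 ± 1801 and 23650 ± 1891. Ribosome biogenesis (median 0.39, 30 of 30 positive, adjusted p = 8.8e-11), ribosomal proteins (0.20, 79 of 79, adjusted p = 1.6e-07), tRNA synthetases (0.17, 20 of 20, adjusted p = 0.0039) and glycolysis (0.27, 20 of 20, adjusted p = 0.039) were higher too. With an estimated correlation the adjusted p = 0.80 for the first 3 and 0.84 for glycolysis. The interferon response was lower, with a median of -0.56 and 21 of 22 negative (adjusted p = 2.6e-05), as were mitochondrial transcripts, with a median of -0.25 and 7 of 7 negative (adjusted p = 0.0027), and 3 enteric neuron genes (median -0.62, adjusted p = 0.042). For these 3 lists the adjusted p = 0.80 with an estimated correlation. The neuron list passed in 6 of 12 fits without single libraries (not without 24 h plus replicate 2 or 3, 24 h min replicate 1, 48 h plus replicate 1 or 2 or 48 h min replicate 2; median -0.24 without 24 h min replicate 1, -0.39 without 24 h plus replicate 2, -0.93 without 24 h min replicate 2 and -1.06 without 24 h plus replicate 1). Glycolysis did not pass without 24 h plus replicate 2 (0.20) or 3 (0.18) or 24 h min replicate 1 (0.05), and had 0.52 without 24 h plus replicate 1 and 0.47 without 24 h min replicate 3. Synthetases did not pass without 24 h plus replicate 2 (0.11) or 24 h min replicate 1 (0.03), and had 0.26 without 24 h plus replicate 1. Mitochondrial transcripts did not pass without 24 h plus replicate 1 (-0.19) or 24 h min replicate 3 (-0.18). The other 4 lists passed without any single library, yet their medians moved. Without 24 h min replicate 1 they were 0.17 for ribosome biogenesis, 0.08 for ribosomal proteins, 0.58 for MAPK output and -0.34 for interferon. Ribosomal proteins had 0.33 and 0.12 without 24 h plus replicates 1 and 2. MAPK output had 0.18 without 24 h plus replicate 1 and 0.21 without 24 h min replicate 3, and interferon -0.32 without 24 h plus replicate 2 and -0.90 without 24 h min replicate 2.

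With the replicate block 1294 genes changed at 24 h, 523 higher and 771 lower, all 6 of the genes above among them, and 14 lists passed. The 6 added were ATF4 targets (0.18, adjusted p = 0.012), glutamine metabolism (0.18, 0.027), the regenerative list (0.24, 0.026) and cholesterol synthesis (0.14, 0.02), all higher, and Lgr5 stem cells (-0.29, 0.017) and 3 immune genes (-0.55, 0.027), both lower. With the block and an estimated correlation their adjusted p was 0.69, 0.37, 0.60, 0.84, 0.60 and 0.31, and the smallest of any list was 0.091. Of the MAPK output list 12 genes rose, of ribosome biogenesis 8, and 7 interferon genes fell. A fit on the 6 samples of that time alone called 0 genes. On approximate reads edgeR called 3 genes, DESeq2 175 and edgeR with the block 1371. At an unadjusted p under 0.05 limma counted 1041 genes, where 738 were due by chance. Without 24 h plus replicate 2 the count was 539, without 24 h min replicate 1 668 and without 24 h plus replicate 3 706. The excess in the fit without the block thus ended in each. The count with the block was 3896 with all samples, and single libraries were not left out there. Rescaling by TMM factors left 3 genes, all higher, where 83.3% of the 6 were higher. Leaving out any 24 h sample but min replicate 1, or 48 h plus replicate 2, 48 h min replicate 2 or 48 h min replicate 3, left 2 or 3 genes.

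After 48 h, 1727 of 14762 genes had changed, 851 higher and 876 lower. Rescaling by TMM factors gave 1017 higher and 797 lower, so which direction held more genes is not fixed. The MAPK output list held 9 genes that rose and none that fell without the block (median 0.54, 20 of 26 positive, adjusted p = 1.9e-05; adjusted p = 0.58 with an estimated correlation). Dusp6 rose from 1388 ± 243 (n = 3) to 3486 ± 611 (n = 3), the membrane protein Emp1 from 3400 ± 1398 to 17290 ± 5527 and Spry4, a second feedback inhibitor, from 26.3 ± 10.5 to 185 ± 45.5 (adjusted p = 0.00323, 0.00374 and 0.00558). Genes of S phase and mitosis were higher by a median of 1.08 with 32 of 32 positive (adjusted p = 1.6e-10; adjusted p = 0.58 with an estimated correlation). Over all genes 5 of them rose, and all 32 passed with p adjusted over the list alone. Bub1 rose from 1085 ± 511 to 2309 ± 41.6 and the replication gene Mcm4 from 4243 ± 1577 to 8028 ± 265, adjusted p = 0.0362 and 0.0344. Without 48 h min replicate 1 the S phase median was 0.54, still past the threshold (0.54 to 1.37 over all single libraries left out). Prm1 was listed at 0 in all 3 min samples and at 186 ± 77.9 in plus, adjusted p = 0.000399.

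Biosynthetic lists were higher at 48 h as well, and each had an adjusted p = 0.58 with an estimated correlation. For ATF4 targets 5 of 31 genes rose (median 0.79, 26 positive, adjusted p = 0.00018), among them Stc2 from 683 ± 71.9 (n = 3) to 2318 ± 789 (n = 3) and Phgdh, the first enzyme of serine synthesis, from 672 ± 206 to 1704 ± 233 (adjusted p = 0.00501 and 0.00652). Of 20 tRNA synthetases 4 rose (median 0.46, 20 positive, adjusted p = 4.6e-06), of 20 genes of glutamine metabolism 3 (0.63, 17 positive, adjusted p = 0.00071), and of 30 genes of ribosome biogenesis 5 (0.61, 30 positive, adjusted p = 3.2e-09), among them Npm1 from 5566 ± 802 to 9031 ± 37.3. Of 79 ribosomal protein genes none passed without the block, yet 79 were positive with a median of 0.45 (adjusted p = 9.6e-10). Of 24 genes of cholesterol synthesis 5 rose (0.61, 24 positive, adjusted p = 1.2e-06), such as Cyp51 from 8715 ± 1901 to 16280 ± 3034, and of 13 genes of fatty acid synthesis 1 rose (0.47, 12 positive, adjusted p = 0.00062). Of 20 glycolysis genes 2 rose (0.93, 20 positive, adjusted p = 0.00032), Hk2, which phosphorylates glucose, from 2166 ± 141 to 3834 ± 603 and the glucose transporter Slc2a1 from 5866 ± 163 to 10140 ± 1901. All these lists passed without any single library, but several medians moved. Without 48 h min replicate 1 they were 0.37 for glycolysis (adjusted p = 0.025), 0.19 for ribosomal proteins, 0.29 for cholesterol synthesis and 0.40 for glutamine metabolism. Without 48 h plus replicate 1 glycolysis had 1.51 and glutamine metabolism 0.95, and without 48 h plus replicate 3 ATF4 targets had 0.47. Glycolysis and glutamine metabolism thus moved in opposite directions without the min or the plus sample of number 1. In each case the partner sample stayed in the fit, so these shifts can reflect a difference between the replicate numbers.

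Interferon genes were lower at 48 h by a median of -1.18, with 22 of 22 negative and 3 that fell over all genes (adjusted p = 4.6e-06; adjusted p = 0.58 with an estimated correlation). Oasl2 fell from 427 ± 153 (n = 3) to 85.0 ± 33.5 (n = 3), and Ifit3 from 48.3 ± 23.5 to 12.3 ± 5.86 (adjusted p = 0.0344 and 0.0484). Lysosomal genes had a median of -0.40, with 20 of 24 negative and 5 that fell (adjusted p = 0.00062; adjusted p = 0.58 with an estimated correlation), such as the protease Ctsa from 5298 ± 899 to 2977 ± 203 and the membrane protein Lamp2 from 12130 ± 2934 to 6012 ± 901. Amino acid transporters did not move as a list (median 0.16, adjusted p = 0.62), but 4 of 21 fell without the block. Slc43a2, another carrier of large neutral amino acids, fell from 1795 ± 356 to 523 ± 202, and Slc38a9, a lysosomal sensor of arginine, from 503 ± 65.9 to 298 ± 34.6 (adjusted p = 0.0101 and 0.0122). Slc7a5 stood at 3827 ± 2119 in min and 8529 ± 3019 in plus, a log2 fold change of 1.30 with an adjusted p = 0.123, and 0.000386 with the replicate block. Slc3a2 stood at 4822 ± 388 and 6999 ± 1681, adjusted p = 0.0615, and 0.00601 with the block. Kras stood at 3224 ± 397 and 3522 ± 259, adjusted p = 0.353. Tuft cell markers Dclk1 (294 ± 184 to 47.3 ± 40.2), Trpm5 (29.7 ± 11.5 to 8.67 ± 3.22) and Pou2f3 (30.3 ± 7.57 to 9.33 ± 4.62) fell, adjusted p = 0.0428, 0.0269 and 0.0315. Their list of 7 did not pass (median 0.31 but direction down in camera, adjusted p = 0.43).

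The largest rises at 48 h after Prm1 included Serpine1, an inhibitor of plasminogen activation, from 201 ± 130 (n = 3) to 3076 ± 2042 (n = 3), and the hormone Stc1, from 47 ± 25 to 671 ± 265 (adjusted p = 0.024 and 0.0122). The basement membrane gene Nid1 rose from 18.0 ± 10.8 to 183 ± 96.4, adjusted p = 0.00678. Among the largest falls were the skeletal muscle actin Acta1, from 1593 ± 516 to 58.3 ± 13.7, and Nrep, from 331 ± 152 to 28.3 ± 6.43, adjusted p = 0.00325 and 0.0024. Ubd, a ubiquitin-like modifier, fell from 127 ± 90 to 4.67 ± 4.04, adjusted p = 0.0197.

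**Figure D3:**
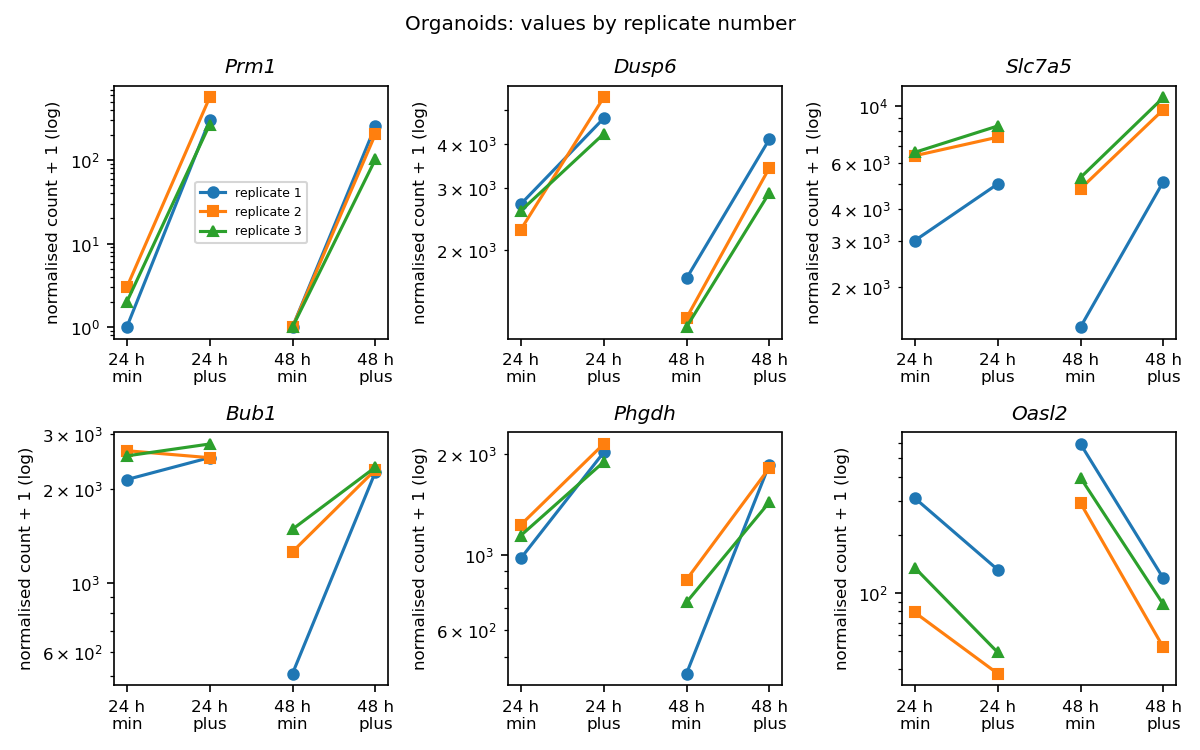
Normalised count plus 1 (log axis, its range set for each gene) of 6 genes in the 12 organoid samples; each line joins the min and plus samples of 1 replicate number at 1 time. Prm1 lies at 0 to 2 in min samples and at 101 to 561 in plus samples, and Dusp6 is higher in plus for every number at both times.

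With the replicate block 7399 genes changed at 48 h (3667 higher, 3732 lower), among them all 1727 with the same direction. In the lists it called 32 S phase genes, 64 ribosomal protein genes, 29 of ribosome biogenesis, 21 of cholesterol synthesis, 18 synthetases and 17 glycolysis genes higher and 19 interferon genes lower. It called 17 MAPK output genes higher and 3 lower, 16 ATF4 targets higher and 2 lower, 14 genes of glutamine metabolism higher and 1 lower, and 10 of fatty acid synthesis higher and 1 lower. For lysosomal genes it called 1 higher and 14 lower, and for amino acid transporters 6 higher and 6 lower. Of the lists 16 passed, the 4 added being oxidative phosphorylation (median 0.21, adjusted p = 0.0023), Wnt targets (-0.48, 0.039), Paneth cells (-1.23, 0.014) and 3 acinar genes (-2.01, 0.043). With the block and an estimated correlation these had an adjusted p = 0.56, 0.49, 0.42 and 0.42, and the smallest of any list was 0.12. A fit on the 6 samples of that time called 2 genes, and leaving out 48 h plus replicate 2 left 376, 48 h plus replicate 3 775, 48 h min replicate 1 890, 24 h plus replicate 3 1115 and 24 h min replicate 3 1138. DESeq2 on approximate reads called 3120 genes and edgeR 1648.

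The difference between the times was tested directly. The log2 fold changes at 24 and 48 h had a Pearson correlation of 0.713 across genes, with the same sign in 79.0%. Of the lists 11 differed, 9 of them higher at 48 h and 2 lower. S phase genes differed by a median of 0.96 with 32 of 32 positive (adjusted p = 3.1e-14; adjusted p = 0.71 with an estimated correlation), cholesterol synthesis by 0.51 with 23 of 24 positive (adjusted p = 4.6e-07; 0.76 likewise) and ATF4 targets by 0.53 with 27 of 31 positive (adjusted p = 0.00019; 0.71 likewise). Lysosomal genes differed by -0.26 with 21 of 24 negative (adjusted p = 8.6e-05; adjusted p = 0.51 with an estimated correlation) and interferon genes by -0.50 with 19 of 22 negative (adjusted p = 0.0046; 0.76 likewise). MAPK output did not pass (0.20, adjusted p = 0.079). The interferon call ended without 24 h plus replicate 1 (median -0.24), 24 h min replicate 2 (-0.29) or 48 h plus replicate 2 (-0.38). Without 48 h min replicate 1 the medians were 0.46 for S phase, 0.15 for cholesterol synthesis, 0.34 for ATF4 targets and -0.32 for interferon, all still past the threshold. ATF4 targets had 0.23 without 48 h plus replicate 3 and 0.87 without 48 h plus replicate 1. With the block 14 lists differed, the 3 added being oxidative phosphorylation (0.18, adjusted p = 0.002), Paneth cells (-0.67, 0.048) and enteroendocrine cells (-0.96, 0.032). With the block and an estimated correlation these had an adjusted p = 0.64, 0.45 and 0.45, and the smallest of any list was 0.23. For single genes 0 of 14762 differed in limma, where 840 had an unadjusted p under 0.05 and 738 were due by chance. That count was 454 and 465 without 24 h min replicates 2 and 3, 496 without 48 h plus replicate 2 and 1272 without 24 h min replicate 1. It was also under 738 without 24 h plus replicate 1 (565), 2 (591) or 3 (709), 48 h plus replicate 3 (603) or 48 h min replicate 1 (698). No excess over chance is therefore claimed for the fit without the block. The count with the block was 3656 with all samples, and single libraries were not left out there. With the block 692 differed (226 higher, 466 lower), among them Stc2 with a log2 difference of 1.03 (adjusted p = 0.0373) and Ctsa with -0.61 (adjusted p = 0.0171). On approximate reads edgeR called 0, with 812 at an unadjusted p under 0.05, DESeq2 39, with 957, and edgeR with the block 680.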

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

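The test of the sex of the mice and that of a sample without the deletion were chosen after the values they rest on had been seen. So were the genes checked next, which were those picked for this text and, added by name, Dbp, Nr1d1, Nr1d2 and Tef. The other tests in this part were set before their results. In the tissue groups of 4 samples, 207 values were checked for a sample far from the other 3 of its group. With about 10 due by chance 15 were found, which is no evidence of an excess for genes picked this way. In the deleted tissue they were Dbp (1630), Nr1d1 (3480), Nr1d2 (1990), Sst (653) and total reads (23.3 M), all in replicate 2, Fos (6710) and Dusp1 (644) in replicate 3 and Igtp (881) in replicate 4. In vehicle tissue they were Galnt12 (937) and Uqcrq (6900) in replicate 2, and Gfap (5) and the share of Gm42418, which overlaps ribosomal RNA (1.4%), in replicate 1. In rapamycin tissue they were Rtp4 (127) and Pla2g4c (134) in replicate 1 and Nr1d1 (2040) in replicate 3. Differences between groups that passed a test of the difference itself were the 692 genes, with the replicate block, and the 11 lists whose plus effect differed between 48 and 24 h, and the 15 lists whose response differed between deletion and rapamycin.

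The first pattern weighed was the list pattern of Slc7a5-deleted tissue, with interferon and ATF4 genes higher and Lgr5 stem cell and S phase genes lower. A single library was tested by leaving out each of the 7, and 28 of 28 medians kept their sign and at least 0.5 of their size, which argues against it. To give the pattern alone, the sex of the mice would need male minus female medians of 1.25, 1.03, -0.74 and -0.29 for interferon, ATF4, Lgr5 stem cell and S phase genes. In the rapamycin experiment, with 3 males and 5 females, the values were 0.32, -0.22, -0.07 and -0.08. So 4 of 4 stayed under 0.5 of the need, also with each library left out, though S phase only just (-0.14 to 0.02). If sex acts alike in both experiments, this argues against it as the whole cause of the pattern in these 4 lists. A part for it stays open. The sex covariate moved the median from 0.94 to 0.50 for interferon and from -0.56 to -0.30 for Lgr5 stem cells. The other lists called after deletion were not tested this way. Of them 3 reversed with sex as a covariate: oxidative phosphorylation (0.28 to -0.03), glycolysis (0.39 to -0.10) and enterocytes (0.30 to -0.12). The rest kept their direction, but enteroendocrine cells (0.33 to 0.05), lysosomal genes (0.14 to 0.06) and Wnt targets (-0.23 to -0.02) shrank and no longer passed. The loss of Slc7a5 may underlie the pattern, as a hypothesis only. Cage, day, time of day and batch are not given in the labels and stay open, untested.

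The second pattern was Prm1, a gene of male germ cells, in plus organoids. RNA of male germ cells would bring Prm2, Tnp1 and Tnp2, which were at 0% of the Prm1 value, listed at 0 in each plus and min group, and this argues against it. Activation of the whole Prm1 region was tested on the 4 tested genes within 200 kb (Clec16a, Socs1, Rmi2 and Litaf), of which 0 were higher at an adjusted p under 0.05. Genes under the filter on low values could not enter this test. With the replicate block, where 7399 of 14762 genes passed at 48 h, Socs1 (adjusted p = 0.038) and Rmi2 (0.0012) were higher and Litaf (4.4e-05) was lower, so a weaker effect on neighbours stays open. A candidate explanation is Prm1 sequence in the construct of the organoids, which could not be tested without the reads.

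The third pattern was the set of clock-controlled genes in replicate 2 of the deleted tissue, where Dbp stood at 1632 against 107 to 187 in the other 3. If the tissue was taken at another phase of the daily clock, 3 further genes had ranks set before they were looked at: Usp2 was highest (1296) and Nfil3 lowest (187) as set, but Wee1 (559) was not highest. With 2 of 3, this explanation stays open, and time of day is not given in the labels. The clock genes Ciart and Wee1 parted all deleted from all AK samples. Ciart stood at 115.9 to 199.5 in deleted and 36.85 to 48.05 in AK tissue, Wee1 at 489.5 to 597.6 and 670.9 to 831.8. The other clock genes looked at overlapped between these groups. Whether time of day differed between the deleted and AK groups as a whole was not tested. A sample without the Slc7a5 deletion was tested first on Slc7a5 itself (1775 against 2613 to 3443 in the 3 AK samples of the same experiment). Trib3 (864 against 336 to 427) and Ddit3 (760 against 280 to 326) lay outside that range too, so 3 of 3 genes did. Both were picked from a fit that counted replicate 2 as deleted, so they are not independent support. In the rapamycin experiment, scaled separately, the 8 samples gave 301 to 481 for Trib3 and 264 to 398 for Ddit3. For Slc7a5 they gave 1700 to 3475, which takes in 1775. Slc7a5 thus argues against a sample without the deletion only within its own experiment. A partial deletion stays open, and a sample without the deletion is not excluded.

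Other splits of the same samples were also fitted. For the 1582 genes at an unadjusted p under 0.05 after deletion, 4 of 35 splits gave at least as many (highest other 2600), and for the 511 after rapamycin 21 of 35 (highest other 3407), so chance cannot be excluded for either. Any split reaches a real count of 0 in limma, so 35 of 35 splits for the deletion (highest other 6) and 35 of 35 for rapamycin (highest other 22) say nothing about chance. The 10 splits of the organoids at a time are too few for a share under 0.05; the real counts were 6 at 24 h and 1727 at 48 h, reached in 1 split each, and the highest other count was 0 at both times. Of these splits 4 part all 3 pairs, the real one included, and the highest count among the others of these was 0 with and without the block. With a real count of 0, nothing follows either for the difference between the times, where 100 of 100 splits drawn gave at least the real 0, nor for that between deletion and rapamycin (100 of 100, highest other 14). At the times, 2223 genes came from a split that kept plus and min apart at 48 h and mixed them at 24 h, a structure of the samples.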

How the results depend on the processing

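Sex as a covariate, the lists and the agreement without single replicates, and the count tools on approximate reads were chosen after seeing the data. The counts of genes changed stayed within 1.5 times with pseudocounts of 0.5 and 5, a mean of at least 50, rescaling by median ratios and the robust prior, in all 6 comparisons. Rescaling moved the median log2 fold change of all genes by at most 0.028.

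For the Slc7a5 deletion, 0 genes became 153 in DESeq2 (74 higher, 79 lower) and 4 in a fit on all 4 tissue groups. Without single replicates the count was 0 to 8, with 8 without deleted replicate 2 and 6 without deleted replicate 1. For rapamycin, DESeq2 on approximate reads gave 14, and for the difference between deletion and rapamycin 22. Without single replicates that difference gave 0 to 7 genes, with 7 without deleted replicate 2 and 2 without rapamycin replicate 3. The correlation between the 2 effects was -0.028 to 0.237 without single replicates, so its sign is not fixed. The cause was not tested.

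At 24 h the 6 genes became 3 without a filter on low values, 3 with TMM factors, 3 in edgeR and 175 in DESeq2 on approximate reads, and 0 in a fit on the 2 groups of the time point. Without single replicates the count was 2 to 9. At 48 h the 1727 genes became 1115 without a filter and 3120 in DESeq2 on approximate reads. A fit on the 2 groups of that time point, with fewer samples, gave 2. Without single replicates the count was 376 to 1984. The difference between the times became 39 genes in DESeq2 on approximate reads. More genes were tested without the filter; for the other settings the cause was not tested.

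The replicate block, which pairs the organoid samples by number, raised the counts to 1294 genes at 24 h, 7399 at 48 h and 692 for the difference between the times, and lists at 24 h from 8 to 14. With edgeR on approximate reads and the block the counts were 1371, 7521 and 680. In the tissues, whose numbers were not taken as pairs, the block left 0 genes for the deletion (1180 at an unadjusted p under 0.05), 0 for rapamycin (478) and 0 for their difference (1687) in limma.

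With the correlation between genes estimated from the data, 0 lists passed in each of the 6 comparisons, so every list result rests on the preset value. Without single replicates 6 to 17 lists passed for rapamycin, 17 without vehicle replicate 4, 14 without rapamycin replicate 2 and 6 without rapamycin replicate 4. At 24 h 5 to 11 passed, with 5 without 24 h plus replicate 2. With sex as a covariate 3 lists called higher after deletion reversed and no longer passed: oxidative phosphorylation (-0.03), glycolysis (-0.10) and enterocytes (-0.12). Enteroendocrine cells (0.05), lysosomal genes (0.06) and Wnt targets (-0.02) kept their direction but no longer passed either. That fit rests on the 1 female deleted sample, and the cause was not tested. Without vehicle replicate 2 the glycolysis list after rapamycin turned to 0.05, and without 48 h min replicate 1 the ribosomal protein list of the difference between the times stood at 0.00, both no longer past the threshold. Of the alternatives on single genes, those that took a value across the threshold were 25 for the deletion, 5 for rapamycin, 29 at 24 h, 15 at 48 h and 9 for the difference between the times to past it, and 46 at 24 h and 240 at 48 h to no longer past it.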

Other observations

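The genes in this part were chosen after their values were seen. The 3 organoid replicate numbers differed from one another in some genes more than plus differed from min. Pdx1, a transcription factor of the duodenum and pancreas, stood at 5 to 14 in the 4 samples of number 2 and at 596 to 866 in the 8 samples of numbers 1 and 3. Fn1, which encodes fibronectin, stood at 68795 to 215784 in number 1 and at 3556 to 39981 in numbers 2 and 3. Cpe, an enzyme that trims peptide hormones, stood at 5070 to 12934 in number 1 and at 340 to 1288 in the others.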
